A study of Homo sapiens with 21 samples.

How the data were processed

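The values analysed were the probe-set intensities of 21 arrays, deposited on a linear scale and hybridised with biotin-labelled cRNA, per the labels' protocols. The software that summarised the probes and the target to which each array was scaled are not given in the sources used here. The intensity scale was therefore read from the values: 2% trimmed means differed between sets of arrays, so they do not share one scale across the series, and per-array medians ran from 12.5 to 23.8. Groups, doses and durations were taken from the labels. For the untreated fibroblast array the title disagrees with the other labels, which were followed, and the array served as a filter and in 1 comparison of the fibroblast arrays in the closing section. The labels mark the repeat arrays as separate samples and do not say whether they came from separate cultures, so the spread between repeats may be technical.

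Values were analysed as log2(value + 16), so fold changes understate the change of weakly expressed genes, with no further normalization. Probe sets were named from the platform table and symbols were updated through Entrez identifiers against a RefSeq gene table. Of 54613 probe sets, 41091 had 1 symbol (41037 matched through Entrez), 1801 had several and 11721 were not named here. Sex-linked markers, HLA genes and genes commonly deleted in people (123 probe sets) were left out, since the hepatocytes come from people. Each gene was represented by the probe set with the highest mean over the 19 co-culture arrays. Of 19712 genes, 13159 lay above the median level of all probe sets. Mouse fibroblast RNA can hybridise to human probes, so a gene was tested only if its mean in the co-cultures lay at least 1 log2 unit above the higher of the 2 fibroblast arrays. That left 5220 genes and removed 60.3% of those above the median. Of the 308 genes called for troglitazone, 85 had more than 1 probe set past the filters on level and fibroblast signal. For 3 of them another such probe set had the opposite sign. Probe sets outside these filters were not compared.

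Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, Benjamini-Hochberg adjustment, adjusted p under 0.05). The planned model held all 19 co-culture arrays, with a level for each duration of experiment [a], a level for experiment [b] and a term per drug, so that all groups share 1 estimate of the spread. Drug terms were assumed equal over the 3 durations. P-values and SE values of this model therefore measure what that assumption and the repeat arrays leave over. Changes of a drug's effect with time are part of that spread. A further fit, chosen after seeing the data, gave a level of its own to the 3 arrays of experiment [a] with a trimmed mean under 100. It brought the median residual SD from 0.425 with 6 residual degrees of freedom to 0.158 with 5. In this fit the change from 24 hours to 7 days rests on the first arrays at 7 days, since both repeats are low-signal arrays. The labels name no such batch, and the set to which the elevated rosiglitazone array belonged was inferred from its signal only. Drugs known for liver injury were compared with their analogs over the 6 drug arrays of experiment [b] with the pair as a block (2 residual degrees of freedom). The difference between times of the troglitazone effect was tested as an interaction.

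The gene lists, the named-gene rule, the planned model and most of the other settings below were fixed before the data were examined. The 25 lists were PPAR targets, PXR and CAR targets, AHR targets, NRF2 targets, the unfolded protein and integrated stress response, cholesterol synthesis, fatty acid synthesis, bile acid synthesis and transport, hepatocyte secreted proteins and identity, acute phase and inflammation, interferon response, oxidative phosphorylation, cell cycle, p53 targets, heat shock, metallothioneins, glucose metabolism, amino acid and urea metabolism, conjugation and other drug metabolism, markers of macrophages, endothelial cells, stellate cells and fibroblasts, cholangiocytes and lymphocytes, and cytoskeleton and dedifferentiation. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. List values in the text are from the fit with a level for the low-signal arrays unless stated. In the planned fit camera called 10 lists up and 2 down for troglitazone, 8 and 1 for rosiglitazone, 10 and 3 for troglitazone minus rosiglitazone, 10 and 3 for elevated rosiglitazone, 3 and 9 at 7 days, 3 and 10 at 14 days, 7 and 4 for ibufenac, 5 and 2 for ibuprofen, 3 and 2 for ibufenac minus ibuprofen, 4 and 0 for entacapone, 2 and 0 for nefazodone and for nefazodone minus buspirone, 1 and 0 for tolcapone and none for buspirone or tolcapone minus entacapone, and none held with an estimated correlation. In experiment [b] the median of each list was also placed among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists hold genes drawn one by one, while the genes of a list vary together (the estimated correlation of fatty acid synthesis was 0.892 in the planned fit and 0.416 with the level below), so a small shared shift on 1 array can place a list beyond all random lists. The genes named were, per comparison, the 10 largest rises and 10 largest falls past the threshold, or the 3 highest and 3 lowest where none passed, up to 4 members per list past the threshold or up to 2 where none passed, and 23 genes fixed for naming. Members of these sets were left out of the text where they repeated others, and genes named beyond the rule (FSCN1, SPARC and GNG11 in every comparison of experiment [b], the endothelial and further macrophage markers, the interferon genes that rose or fell by 14 days, and CD163 and CD14 outside their list) were chosen after their values were seen. Some of the genes fixed for naming are not reported here. Probe sets of multigene families can cross-hybridise.

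Gene calls in 4 comparisons, and camera with its preset correlation, were tested on simulated data, in which noise with the fitted spread was added to the fitted levels of the 5220 genes, including the offset of the low-signal arrays, and 100 genes each were changed 1.5-fold and 2-fold. For troglitazone against DMSO the planned fit recovered 0 of 100 at either size, and the fit with a level for the low-signal arrays 65 and 94, with 7 unchanged genes called. For elevated rosiglitazone it recovered 4 and 48 (3 unchanged called), for 14 days against 24 hours 59 and 85 (4 unchanged called), where the planned fit recovered 0 at either size, and for the hepatotoxins against analogs 80 and 95 (12 unchanged called). The simulations of experiment [a] used the levels and spread of the fit with the level for the low-signal arrays, which favours that fit. Noise was independent between genes and drug effects were equal over time. The data need not follow this, so these rates may not hold for the real calls. The alternatives tried were quantile normalization, no filter on level or on fibroblast signal, other pseudocounts, an intensity trend in eBayes, every probe set, a 2-fold minimum, only the 2 groups compared, a block for replicate number, and each array left out in turn. Those added after seeing the data were the level for the low-signal arrays, with the same alternatives under it, and leaving out those 3 arrays or all arrays of a duration. Among DMSO arrays at 7 days, 282 genes differed by at least 2-fold after median centring between the first array of experiment [a] and its repeat, 303 between that first array and the array of experiment [b], and 418 between the repeat and the array of experiment [b]. The experiments were not compared directly.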

Results

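Gene expression was measured on 21 Affymetrix arrays to follow how human liver cultures respond to drugs given for days. The cultures were micropatterned co-cultures, in which primary human hepatocytes grow in islands surrounded by mouse 3T3-J2 fibroblasts that help to keep hepatocyte functions. Experiment [a] held 12 co-culture arrays. Treatment with the solvent DMSO (0.1%), with rosiglitazone at 0.373 µg/mL or with troglitazone at 2.82 µg/mL lasted 24 hours, 7 days or 14 days, and 1 further array was treated for 7 days with rosiglitazone raised to 2.82 µg/mL. Experiment [b] held 7 co-culture arrays, all treated for 7 days with DMSO, buspirone, nefazodone, ibuprofen, ibufenac, entacapone or tolcapone. A further 2 arrays held the mouse fibroblasts alone.

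Of the 19 groups, 17 had 1 array, and 7-day DMSO and 7-day troglitazone of experiment [a] had 2. The number of arrays limits the precision of every value below, and single-array groups have no replicate check of their own. The signal differed between sets of arrays. The 2% trimmed mean signal of an array was 70.7 to 72.9 on 3 arrays of experiment [a], which were the repeat arrays of 7-day DMSO and troglitazone and the array of elevated rosiglitazone. On the other 9 co-culture arrays of that experiment it was 130 to 148, in experiment [b] 114 to 119, and on the fibroblast arrays 53.2 to 53.8. Across probe sets, the 3 low-signal arrays correlated with each other at 0.985 to 0.99 and with the other 9 at 0.918 to 0.946. Counts are therefore given from the planned fit and from a fit in which these 3 arrays had a level of their own, a choice made after seeing the data.

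Troglitazone, a thiazolidinedione withdrawn as an antidiabetic drug because of liver injury, was compared with DMSO over 4 arrays each. The largest rises included genes of drug metabolism and lipid synthesis. THRSP, a regulator of lipogenesis, was 10.3-fold higher with troglitazone (log2 difference 3.36, SE 0.70, limma adjusted p = 0.0441, higher in 4 of 4 pairs). This value pools pairs that differed widely with time. The THRSP signal fell with time under both treatments, and far more with DMSO. CYP2B6, a cytochrome P450 induced through the xenobiotic receptors CAR and PXR, was 7.89-fold higher (log2 2.98, SE 0.45, limma adjusted p = 0.0335, 4 of 4 pairs). FABP4, the fatty acid binding protein of fat cells and a target of the receptor PPARG, rose by 1.72 on the log2 scale (SE 0.18, limma adjusted p = 0.013, 4 of 4 pairs), and CD14, a co-receptor for bacterial lipopolysaccharide made by hepatocytes and macrophages, by 1.70 (SE 0.20, limma adjusted p = 0.013). The scavenger receptor CD163, a macrophage marker, was 3.27-fold lower (log2 -1.71, SE 0.31, limma adjusted p = 0.0417, lower in 4 of 4 pairs).

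These values and the following ones come from the fit with a level for the low-signal arrays. The other genes with the largest rises were CYP2C8 at 2.56 (SE 0.57), the glycerolipid enzyme GPAM at 2.37, CYP3A7-CYP3A51P at 2.12, the complement lectin MBL2 at 1.84, the retinol dehydrogenase RDH16 at 1.71 and CYP3A4, the main drug-oxidising P450 of adult liver, at 1.67 (SE 0.36). RDH16 was higher in 3 of 4 pairs, the others in 4 of 4. The probe sets of CYP3A4 and CYP3A7-CYP3A51P can cross-hybridise, so their values are not separate evidence. The largest falls after CD163 were in TCIM at -1.66, LOC154761 at -1.38, the epithelial protein S100A14 at -1.27, the neutrophil chemokine CXCL2 at -1.26, ISG20 at -1.25, ARL14 at -1.22, MIDN at -1.22 (3 of 4 pairs) and the cytokine IL18 at -1.20. CRCT1, a gene of the epidermal differentiation cluster, was lowest at -2.19 (SE 0.43). CRCT1 and ARL14 read under 2-fold the higher fibroblast signal on several arrays, so their sizes depend on the value added before taking logs.

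Among the fixed gene lists, the targets of PXR and CAR had a median log2 difference of 0.80, with 10 of 15 measured genes raised over all genes tested and 13 adjusted over the list alone. Of 25 measured PPAR targets, which handle lipid, 11 were raised (15 adjusted over the list alone, median 0.52), among them the fatty acid hydroxylase CYP4A11 at 1.01 and the acyl-CoA synthetase ACSL1 at 0.70. PDK4, PLIN2 and CPT1A, further PPAR targets, did not pass, at 0.59 (SE 0.28), 0.17 (SE 0.15) and 0.02 (SE 0.12). In fatty acid synthesis 9 of 16 genes were raised (13 adjusted over the list alone, median 0.74), with FASN, the fatty acid synthase, at 1.35 and the desaturase SCD at 1.12. In cholesterol synthesis 7 of 17 were raised (15 adjusted over the list alone, median 0.68), such as TMEM97 at 1.35, the sterol-regulated INSIG1 at 0.87, DHCR7 at 0.86 and HMGCS1 at 0.84. Among bile acid genes 4 of 20 were raised (9 adjusted over the list alone, median 0.37), including AKR1D1 at 1.12 and SLC27A5 at 1.08. With DMSO, SLC27A5 read 80.7 at 14 days and 56.7 on the repeat array, against a higher fibroblast signal of 61.6. The size of its rise is therefore limited by background. CYP7A1, the rate-limiting enzyme of bile acid synthesis, did not pass at 1.35 (SE 0.43, limma adjusted p = 0.0761), nor did the bile salt export pump ABCB11 at 0.22 (SE 0.18).

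Of 24 genes of the unfolded protein and integrated stress response, 6 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.34). Those raised included the serine synthesis enzymes PHGDH at 1.63 and PSAT1 at 0.80, the stress transcription factor ATF5 at 1.31, the chaperone HSP90B1 at 0.68 and the pseudokinase TRIB3 at 0.64. HSP90B1 passed the filter through experiment [b], where it read 638 to 729. In experiment [a] only the first 7-day troglitazone array, at 264, exceeded 2-fold the higher fibroblast signal of 115. Its DMSO arrays read 39.1 to 179, so mouse RNA may hold part of its value. In conjugation and other drug metabolism all 30 measured genes had positive values, with 4 past the test (9 adjusted over the list alone, median 0.28), such as CYP39A1 at 1.49 and ALDH2 at 0.88. The hepatocyte list had 1 of 27 genes raised, CEBPA at 0.68 (1 adjusted over the list alone, median 0.25). ALB, albumin, differed by 0.03 (SE 0.08), at signals close to the highest on each array, where a change can be compressed. Amino acid and urea metabolism had 0 of 24 genes past limma's test and 7 adjusted over the list alone (median 0.27). In the list of cytoskeleton and dedifferentiation 2 of 14 genes fell and 13 were negative (7 adjusted over the list alone, median -0.36), with the tropomyosin TPM1 at -0.78. These 10 lists stood apart from the other genes by camera with its preset correlation, with adjusted p from 4.9e-09 to 0.00053. None held when the correlation was estimated (adjusted p = 0.417 to 0.471 with an estimated correlation). Camera asks whether a list's genes move more than other genes do.

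The other lists were not called in this fit. Camera also called, in the planned fit, glucose metabolism up (adjusted p = 0.0157) and cholangiocyte markers down (adjusted p = 0.0024), and neither held (adjusted p = 0.658 and 0.482 with an estimated correlation). Of 18 NRF2 targets, which counter oxidants and electrophiles, 2 rose and 1 fell (median -0.01), with ME1 at 0.87 and the glutathione synthesis enzyme GCLC at -0.65. The 4 AHR targets had a median of -0.08, the 57 genes of oxidative phosphorylation 0.03, the 10 heat shock genes -0.02, the 6 cell cycle genes -0.20, the 6 metallothioneins -0.22 and the 14 p53 targets -0.20. GDF15, a stress-induced cytokine, did not pass at -0.77 (SE 0.21, limma adjusted p = 0.0587). Of 16 acute phase genes 1 rose and 1 fell (median -0.04), of 16 interferon genes 3 rose and 1 fell (median -0.01), and of 15 glucose genes 1, PCK1 at 0.93, rose (median 0.12). Of the marker lists, 4 macrophage genes had a median of 0.41, 2 stellate cell genes -0.15 and 7 cholangiocyte genes -0.47, with KRT19, a bile duct keratin, at -1.09 and not past the test. Endothelial and lymphocyte markers had 0 tested genes, because none rose far enough above the fibroblast arrays.

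In the planned fit, limma called 4 genes for troglitazone, CYP2B6 and CYP2C8 up and CD163 and CRCT1 down, with 269 genes at an unadjusted p under 0.05. With a level for the low-signal arrays it called 308 (214 up, 94 down), of which 59 differed by at least 2-fold and 205 rises and 90 falls had the same sign in all 4 pairs. After quantile normalization that fit called 317 up and 234 down (57.5% higher against 69.5%). Without the 3 low-signal arrays the planned fit called 2 genes. The 308 calls depended on single arrays. Without the DMSO, rosiglitazone or troglitazone array at 24 hours the fit called 1490, 6 and 1907 genes. Without the corresponding array at 7 days it called 0, 6 and 1, at 14 days 5, 6 and 5, and without either the repeat DMSO or the repeat troglitazone array 2. Without all arrays at 24 hours it called 1883 (713 up, 1170 down), without those at 7 days 0 and without those at 14 days 1. The planned count ranged from 1 without the 14-day troglitazone array or the repeat DMSO array to 122 without the repeat troglitazone array. It was 22, 18 and 23 without DMSO, rosiglitazone or troglitazone at 24 hours, 31, 29 and 8 at 7 days, and 2 and 18 without DMSO or rosiglitazone at 14 days.

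By time of treatment, CYP3A4 differed between troglitazone and DMSO by 0.56 at 24 hours, 0.98 and 1.79 in the 2 pairs at 7 days, and 3.33 at 14 days. Its DMSO signal went from 9920 at 24 hours to 7310 at 7 days and 1410 at 14 days, against 14700, 14500 and 14300 with troglitazone, signals in the upper range of the arrays, where a change can be compressed. CYP2B6 differed by 2.15, 1.997, 2.56 and 5.21 in the same order, and CYP2C8 by 0.67, 2.39, 2.01 and 5.15. FABP4 differed by 1.92 already at 24 hours and by 1.64, 1.04 and 2.26 later. With DMSO, THRSP went from 9650 at 24 hours to 1130 on the first array at 7 days and 49.2 at 14 days. With troglitazone it read 12000, 9400 and 4090. On the repeat arrays at 7 days it read 71.4 with DMSO and 1510 with troglitazone. The median of the PXR and CAR targets was 0.31, 0.78, 0.97 and 1.36, and that of cholesterol synthesis 0.09, 0.58, 0.65 and 1.06. The difference between 24 hours and the later times was tested gene by gene with limma, which called 0 genes, with 1184 at an unadjusted p under 0.05, of which 985 differed less at 24 hours.

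**Figure D1:**
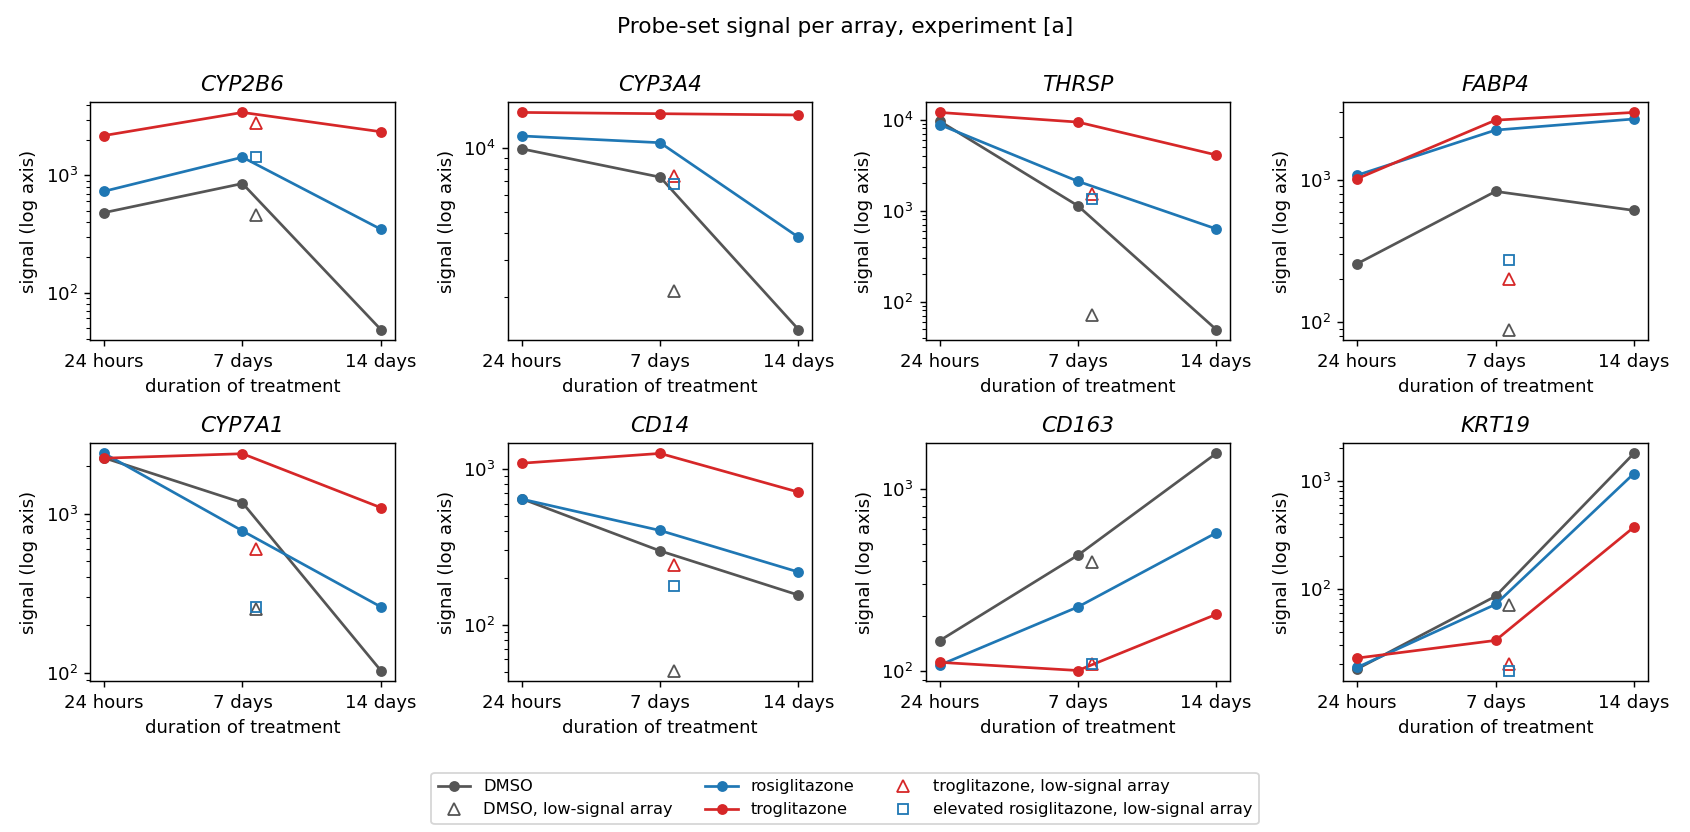
Probe-set signal on each array of experiment [a] (log axis) against duration of treatment for 8 genes, with lines joining the arrays of DMSO, rosiglitazone and troglitazone and open symbols for the 3 low-signal arrays at 7 days. CYP3A4 reads 14300 to 14700 with troglitazone on the arrays outside the low-signal set and 7390 on the low-signal one, while its DMSO signal is 1410 at 14 days, and CD163 reaches 1560 with DMSO against 205 with troglitazone.

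Rosiglitazone, a thiazolidinedione that shares the PPARG target of troglitazone and has caused far less liver injury in patients, was compared with DMSO at 0.373 µg/mL over 3 arrays. FABP4 had the largest value, 1.73 (SE 0.20, limma adjusted p = 0.0626, higher in 3 of 3 pairs), and did not pass. CYP2C8 at 1.496 (SE 0.64) and THRSP at 1.48 (SE 0.79) followed. The lowest values were SLC24A1 at -1.19 (with a signal of 14.6 at 14 days, under that of the fibroblasts), MTCL1 at -1.10 and ZNF766 at -0.92, also not past the test. CD163 was at -0.90 (SE 0.35) and CD14 at 0.33 (SE 0.22). PPAR targets had a median of 0.28, PXR and CAR targets 0.39, fatty acid synthesis 0.25 and conjugation 0.20, and 1 gene each of the PPAR and the PXR and CAR lists passed when adjusted over the list alone. Camera called 8 lists up, the others being bile acid genes, hepatocyte genes, amino acid metabolism and the stress response list, and cytoskeleton genes down, with adjusted p from 5.16e-11 to 0.0399. None of these calls held (adjusted p = 0.826 to 0.834 with an estimated correlation). Limma called 0 genes in either fit, with 31 at an unadjusted p under 0.05 in the planned fit and 131 with a level for the low-signal arrays. Without the 3 low-signal arrays it called 1 gene. In the planned fit it called 1 without the first 7-day DMSO or troglitazone array and 5 without the repeat troglitazone array, and with the level for the low-signal arrays 1 without either repeat array.

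Troglitazone and rosiglitazone differ in structure, since troglitazone carries the chromane ring of vitamin E where rosiglitazone carries an aminopyridine. Their doses differed here at 2.82 and 0.373 µg/mL. The largest values of troglitazone minus rosiglitazone were THRSP at 1.88 (95% interval 0.10 to 3.66), CYP2B6 at 1.78 (0.65 to 2.90) and GPAM at 1.47, and the lowest CRCT1 at -1.57, the cardiac and stress gene ANKRD1 at -1.34 and TCIM at -1.32. CD14 was 1.37 higher (SE 0.23, limma adjusted p = 0.257). FABP4 differed by -0.01 (95% interval -0.46 to 0.44). None passed. Cholesterol synthesis stood 0.53 higher with troglitazone (12 of 17 genes adjusted over the list alone), PXR and CAR targets 0.65 (6 of 15), fatty acid synthesis 0.49 (5 of 16), and macrophage markers 0.32. Camera called 10 lists up and 2, cytoskeleton genes (-0.29) and metallothioneins (-0.15), down. No call held (adjusted p = 0.327 to 0.553 with an estimated correlation). Limma called 0 genes in either fit, with 87 and 634 at an unadjusted p under 0.05. With the level for the low-signal arrays it called 680 genes (201 up, 479 down) without the 24-hour troglitazone array and 168 without all arrays at 24 hours, and in the planned fit 2 without the repeat troglitazone array.

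Rosiglitazone raised to 2.82 µg/mL, the dose of troglitazone, was measured on 1 array at 7 days. Against DMSO it had THRSP at 3.56 (SE 1.27), PHGDH at 2.32 (SE 0.52), CYP2C8 at 2.22 (SE 1.03), FABP4 at 1.80 (SE 0.32) and CD14 at 1.41 (SE 0.36). CRCT1 was at -2.03, CD163 at -1.71 (SE 0.56) and ID3, an inhibitor of differentiation factors, at -1.59. The DMSO level behind these values is fitted from both repeat arrays with the pooled troglitazone term. On the repeat DMSO array FABP4 read 89 and CD14 50.8, under 2-fold the higher fibroblast signals of 67.7 and 28.5. ID3 read 132 on the elevated array, against 71.1, so the sizes for these genes are limited by background. The 25 PPAR targets had a median of 0.58 (3 adjusted over the list alone), PXR and CAR targets 0.62 (2 adjusted over the list alone), fatty acid synthesis 0.59, cholesterol synthesis 0.34, conjugation 0.33, cytoskeleton genes -0.34 and cholangiocyte markers -0.49. Camera called 9 lists up and 2 down, none of which held (adjusted p = 0.319 to 0.504 with an estimated correlation). Limma called 0 genes in either fit, with 155 and 262 at an unadjusted p under 0.05, and 56 genes differed by at least 2-fold with the level for the low-signal arrays. In the planned fit the median of all genes was -0.57, and 91 genes were called without the repeat troglitazone array.

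At this matched dose of 2.82 µg/mL, no gene passed the test of the difference between troglitazone and rosiglitazone. The time was not matched, since the troglitazone term is pooled over 24 hours, 7 days and 14 days and elevated rosiglitazone was measured at 7 days only. The values below can thus differ from those of the low-signal 7-day arrays, where FABP4 read 200 with troglitazone and 273 with elevated rosiglitazone. CYP7A1 was 1.23 higher with troglitazone (95% interval -0.53 to 2.98), the adaptor gene LAT2 1.22 higher (0.06 to 2.39) and CYP2B6 1.14 higher (-0.68 to 2.96). The lipid droplet gene CIDEC was at -0.91 (-2.58 to 0.76), the cholesterol transporter ABCG1 at -0.75 (-1.64 to 0.14) and PHGDH at -0.70 (-1.88 to 0.48). FABP4 differed by -0.08 (-0.81 to 0.65) and CYP3A4 by 0.06 (-1.42 to 1.54). Except for FABP4, the intervals of these genes leave room for differences of 2-fold or more. Of the lists, camera called cholesterol synthesis alone in the fit with a level for the low-signal arrays (median 0.28 higher with troglitazone, positive in 16 of 17 genes, adjusted p = 0.000822), with its regulator SREBF2 at 0.60 (0.19 to 1.02), and the call did not hold (adjusted p = 0.946 with an estimated correlation). Camera called 5 lists up and 1 down in the planned fit, none of which held (adjusted p = 0.964 with an estimated correlation). Limma called 0 genes in either fit, with 63 and 35 at an unadjusted p under 0.05, and 4 genes were at least 2-fold higher. The planned fit, in which the median of all genes was 0.53, called 238 without the repeat troglitazone array.

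**Figure D2:**
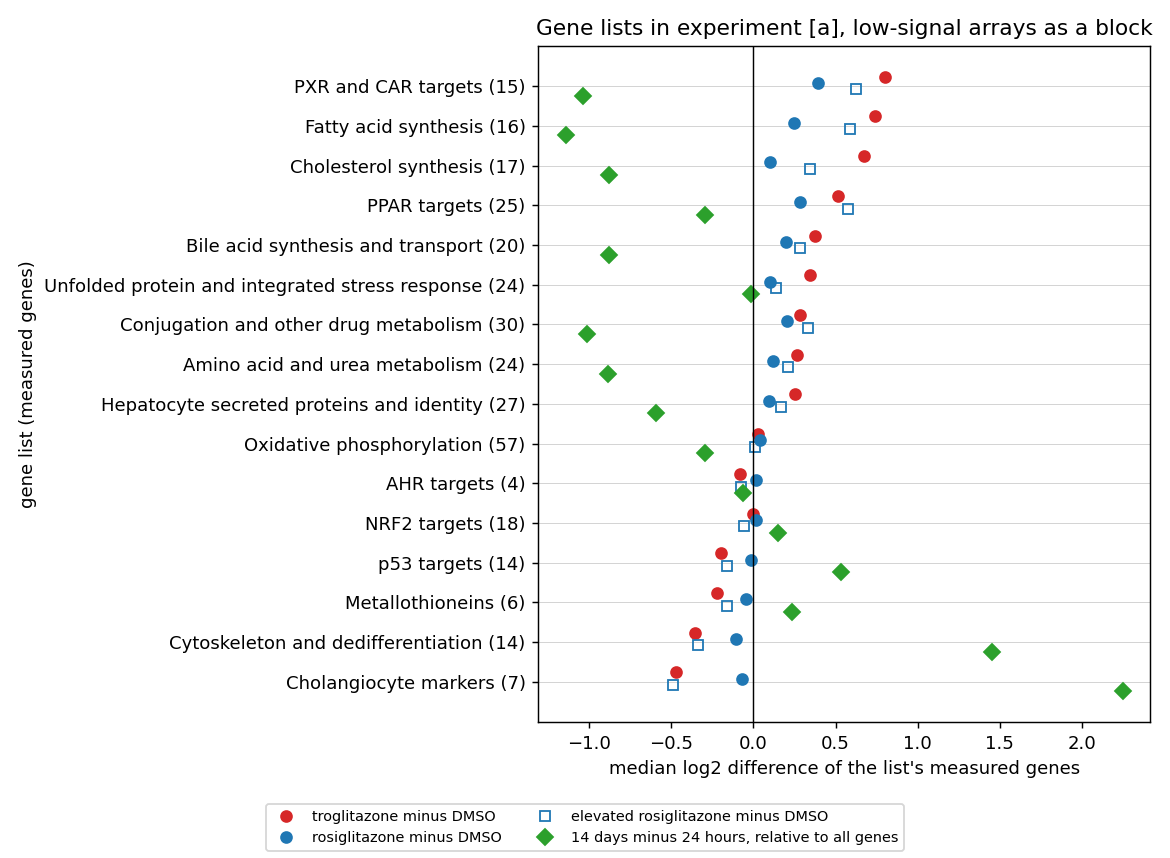
Median log2 difference of the measured genes of 16 gene lists (number of genes in parentheses) in the comparisons of troglitazone, rosiglitazone and elevated rosiglitazone with DMSO, and of 14 days with 24 hours relative to the median of all genes, each from the fit with a level for the low-signal arrays. PXR and CAR targets lie at 0.80 with troglitazone, 0.39 with rosiglitazone and 0.62 with elevated rosiglitazone, against -1.04 from 24 hours to 14 days.

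Time in culture was compared over all treatments of experiment [a], with the change assumed equal in each. The median of all genes was 0.29 higher at both later times with a level for the low-signal arrays, and 0.14 at 7 days and 0.12 at 14 days after quantile normalization, so values are given relative to it unless stated, whereas the test and the counts of genes that rose or fell refer to the change itself. From 24 hours to 14 days, the largest rises included genes of bile duct cells and of the cytoskeleton. CRCT1 rose by 5.95 on the log2 scale (SE 0.50, limma adjusted p = 3.82e-05), the keratins KRT19 by 4.43 (SE 0.35, limma adjusted p = 3.29e-05) and KRT7 by 4.36, the tight junction gene CLDN4 by 3.85 and TAGLN, an actin-binding gene of smooth muscle and activated stellate cells, by 3.78. The others were ID3 at 4.69, the laminin-related NTN4 at 4.05, IGFBP1 at 4.03, ANKRD1 at 4.01 and GDF15 at 3.72. The largest falls were in DIO1, which activates thyroid hormone, at -4.49 (SE 0.36, limma adjusted p = 4.87e-05), THRSP at -4.46, MBL2 at -4.32, SERPINA5 at -3.76, the alcohol dehydrogenase ADH4 at -3.75, SPP2 at -3.72, PGLYRP2 at -3.18, SLC3A1 at -3.10, CYP7A1 at -3.08 and TCEA2 at -3.08. CYP3A4 fell by 1.75 (SE 0.42) and CYP2C8 by 2.60 (SE 0.66), whereas ALB, close to the highest signal on each array, did not pass, at -0.05 before the median of all genes is subtracted. CD163 rose by 1.82 and CD14 fell by 1.63. The changes of CYP3A4, CYP2C8, CD163, CD14, THRSP, CYP7A1 and KRT19 average treatments whose courses differed, and those of other genes named here may do so too. From 24 hours to 14 days CYP3A4 went from 9920 to 1410 with DMSO and from 14700 to 14300 with troglitazone. CYP2C8 went from 5860 to 183 and from 9330 to 7070, CD163 from 147 to 1560 and from 112 to 205, and CD14 from 644 to 155 and from 1090 to 711. CYP7A1 went from 2240 to 103 with DMSO and from 2230 to 1090 with troglitazone. The signals of THRSP and KRT19 are given under the other observations. At 24 hours CRCT1, CLDN4, KRT7, KRT19 and TAGLN read 1.54 to 25, near the fibroblast signal or near the median of all probe sets, ID3 lay under the higher fibroblast signal, and at 14 days SPP2, PGLYRP2 and TCEA2 read under 2-fold the higher fibroblast signal with DMSO, so the sizes of these changes and their order depend on the value added before taking logs.

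In groups, all 14 measured genes of cytoskeleton and dedifferentiation rose by 14 days (median 1.46 relative to all genes), as did 6 of 7 cholangiocyte markers (median 2.25). In conjugation and other drug metabolism 2 genes rose and 19 of 30 fell (median -1.01), in amino acid and urea metabolism 16 of 24 fell (median -0.89), in cholesterol synthesis 13 of 17 (median -0.88), in fatty acid synthesis 2 rose and 11 of 16 fell (median -1.14), in bile acid genes 3 rose and 11 of 20 fell (median -0.88), among PXR and CAR targets 1 rose and 8 of 15 fell (median -1.04), and in the hepatocyte list 1 rose and 13 of 27 fell (median -0.59). The inflammatory chemokines CXCL8 and CXCL2 rose by 3.70 and 3.54, the small heat shock protein HSPB1 by 2.51 and SLC7A11, the cystine transporter of the NRF2 response, by 2.12. Camera called 2 lists up and 10 down at 14 days, the others being oxidative phosphorylation, cell cycle and glucose metabolism, and no call held (adjusted p = 0.305 to 0.661 with an estimated correlation). With the level, the 7-day change rests on the 3 first arrays at 7 days. There IGFBP1 rose by 3.25 (SE 0.33), NPIPA1 by 2.40, GDF15 by 2.34 and ID3 by 2.31, while OAT, which breaks down ornithine, fell by 3.28 (SE 0.29), MBL2 by 3.13, DIO1 by 2.26 and the methyltransferase GNMT by 2.23. The low-signal repeats did not share all of these. OAT read 615 and 963 on the repeat DMSO and troglitazone arrays, against 95.8 to 270 on the first arrays and 1110 to 1390 at 24 hours, and NPIPA1 47.9 and 66.5, against 320 to 518 and 35.4 to 54.7. On the first arrays all 6 metallothioneins, 12 of 14 cytoskeleton genes, 7 of 10 heat shock genes and 11 of 14 p53 targets rose by 7 days, against 2277 of all 5220 genes (medians 0.30, 0.41, 0.34 and 0.31 relative to all genes). On the repeats MT1M read 205 and 138 against 557 to 833 at 24 hours and MT1G 1880 and 1270 against 5590 to 6720, lower by more than the scale of these arrays. Camera called these 4 lists up and 10 down, none of which held (adjusted p = 0.365 to 0.551 with an estimated correlation).

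In the planned fit limma called 92 genes at 7 days (51 up, 41 down, 55.4% higher) and 591 at 14 days (431 up, 160 down, 72.9% higher), against 79.4% and 62.4% higher after quantile normalization. With a level for the low-signal arrays it called 2538 at 7 days (2277 up, 261 down) and 3234 at 14 days (2478 up, 756 down), and 2194 genes were called at both times in the same direction. Without the 3 low-signal arrays the planned fit called 2312 and 3128. In the planned fit, leaving out DMSO at 24 hours gave 2 genes at 7 days and 231 at 14 days, rosiglitazone at 24 hours 42 and 275, and the repeat troglitazone array 236 and 1015. At 7 days it gave 175 without the first DMSO and 204 without the first troglitazone array, and at 14 days 246, 351 and 382 without DMSO, rosiglitazone or troglitazone at 14 days and 961 without the repeat DMSO array. With the level for the low-signal arrays, the count at 7 days was 1618 without DMSO and 1192 without rosiglitazone at 24 hours, and 1203 without DMSO and 1105 without rosiglitazone at 7 days.

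Experiment [b] set 3 drugs known for liver injury beside structural or functional analogs known to be safer for the liver, an assignment that rests on general knowledge of these drugs. Each drug had 1 array and all were compared with the same DMSO array. The model fits each of these arrays exactly, so experiment [b] adds nothing to the estimate of the spread. SE values, intervals and tests for single drugs and single pairs therefore rest on the spread of experiment [a], which includes changes of drug effects with time. They do not measure the uncertainty of the arrays of experiment [b]. Only the comparison across the 3 pairs has a spread from experiment [b]. Limma called 0 genes for each drug and each pair in either fit. SE values are from the fit with a level for the low-signal arrays of experiment [a]. In experiment [a] SPARC read 4.83 to 25, against a higher fibroblast signal of 13.4. GNG11 read 2 to 23.2 there outside the low-signal arrays, against 16.8. The SE values, intervals and tests of these 2 genes thus rest on signals near background and may understate the spread of an expressed gene. Random lists do not share the correlation between the genes of a list, so a place beyond all of them is not a test of the drug.

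Nefazodone, an antidepressant given here at 434.55 ng/mL, had FSCN1, an actin-bundling gene, at 1.69 (SE 0.41), the matrix gene SPARC at 1.65 (SE 0.24, limma adjusted p = 0.388) and the G-protein gene GNG11 at 1.39, with S100P at -1.04, SNAPC3 at -0.95 and CAPN12 at -0.92. On the same array the 4 endothelial markers with at least 2-fold the fibroblast signal, outside the tested genes, had a median of 1.26 above DMSO. The PXR and CAR targets had a median of 0.11, above all of 10000 random lists of like expression (central 95% -0.14 to 0.00), with CYP3A4 at 0.71 (SE 0.72). Fatty acid synthesis was at -0.21, at percentile 0.02 of random lists, and cytoskeleton genes at 0.12. Camera calls did not hold (adjusted p = 0.913 with an estimated correlation). Limma gave 2 genes at an unadjusted p under 0.05 in the planned fit and 42 with the level for the low-signal arrays, and 5 genes differed by at least 2-fold. Buspirone, an anxiolytic at 2.11 ng/mL, had COPB2-DT at 0.98, NUDT16L1 at 0.69 and TAGLN at 0.67 (both under 2-fold the higher fibroblast signal with DMSO), with MLKL, the effector of necroptosis, at -2.38 (SE 0.43, at a signal of 8.02 near that of the fibroblasts, so its size depends on the value added before taking logs) and CNNM3 at -0.83. Its endothelial median was 0.12 and its 6 cell cycle genes had a median of -0.23, at percentile 0.31. Camera called no list, 1 and 20 genes had an unadjusted p under 0.05, and 1 gene differed by 2-fold.

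The doses of nefazodone and buspirone, which share an arylpiperazine group, differed. Between them MLKL, near the fibroblast signal with buspirone, was 2.03 higher with nefazodone (95% interval 1.05 to 3.01), FSCN1 1.69 higher (0.77 to 2.60) and GNG11 1.49 higher (0.57 to 2.41), and S100P was at -1.01 (-2.39 to 0.37), PRMT3 at -0.79 (-1.43 to -0.14) and IGFBP1 at -0.69 (-1.97 to 0.60). CYP3A4 differed by 0.75 (-0.90 to 2.39). PXR and CAR targets stood 0.20 higher with nefazodone, above all random lists, and fatty acid synthesis at -0.18, below all of them. Camera called the former (adjusted p = 6.57e-07), which did not hold (adjusted p = 0.716 with an estimated correlation). It also called oxidative phosphorylation and cytoskeleton genes (adjusted p = 0.0466 for both, and adjusted p = 0.996 with an estimated correlation). The median of the cytoskeleton list, -0.01, has the opposite sign to camera's call. Limma gave 3 and 20 genes at an unadjusted p under 0.05, and 6 genes differed by at least 2-fold.

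Ibufenac, an anti-inflammatory drug at 19.23 µg/mL, had a PPAR target median of 0.45 and a fatty acid synthesis median of 0.47, both above all random lists (central 95% up to 0.04 and 0.07), with PDK4, which restrains pyruvate oxidation, at 1.31 (SE 0.56) and PLIN2, a lipid droplet coat protein, at 0.95 (SE 0.30). S100P was at 1.40 and CYP2B6 at 1.09 (SE 0.89). MLKL was at -1.85, the chemokines CXCL6 and CXCL2 at -1.38 and -1.24 and the mitochondrial gene COX3 at -1.36. Acute phase genes had a median of -0.25, at percentile 0.02, metallothioneins 0.22 and NRF2 targets 0.18, and endothelial markers -0.30. Camera calls did not hold (adjusted p = 0.56 with an estimated correlation). Limma gave 4 and 115 genes at an unadjusted p under 0.05, and 13 differed by at least 2-fold. Ibuprofen, at 31.87 µg/mL, had a PPAR target median of 0.25, also above all random lists, PLIN2 at 0.86 (SE 0.30), CIDEC at 0.93 and NUDT16L1 at 0.94 (near background with DMSO), with MLKL at -2.34 (signal 8.68), TESC at -1.10 and CXCL6 at -0.90. Amino acid metabolism was at -0.20, below all random lists, and acute phase genes at -0.20, at percentile 0.05. Its endothelial median was -0.01. Camera calls did not hold (adjusted p = 0.691 with an estimated correlation), 1 and 33 genes had an unadjusted p under 0.05, and 2 differed by at least 2-fold.

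Ibuprofen carries a methyl group beside the acid that ibufenac lacks, and the doses differed. Ibufenac minus ibuprofen was 0.81 for THRSP (95% interval -2.37 to 3.99), 0.79 for S100P (-0.59 to 2.17) and 0.71 for ACKR2, with DYRK3 at -0.92 (-1.70 to -0.15), the interferon-induced IFI6 at -0.91 (-2.17 to 0.35) and VPS53 at -0.83 (-1.49 to -0.17). ACKR2 with ibuprofen, and DYRK3 and IFI6 with ibufenac, read under 2-fold the higher fibroblast signal, so these sizes and ranks depend on the value added before taking logs. PDK4 differed by 0.63 (-0.63 to 1.90). Fatty acid synthesis was 0.31 higher with ibufenac, above all random lists (camera adjusted p = 0.015), and acute phase genes at -0.19, below all of them (camera adjusted p = 0.00234). Neither held (adjusted p = 0.976 with an estimated correlation). Limma gave 0 and 29 genes at an unadjusted p under 0.05, and 0 differed by 2-fold.

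Tolcapone at 4.51 µg/mL and entacapone at 1.91 µg/mL are nitrocatechol inhibitors of catechol-O-methyltransferase used in Parkinson's disease. Tolcapone had FSCN1 at 1.96 (SE 0.41), SPARC at 1.91 (SE 0.24, limma adjusted p = 0.124) and GNG11 at 1.60 (SE 0.41), and the endothelial markers a median of 1.40. CNNM3 was at -1.09, the centrosome tubulin TUBG1 at -1.08 and PTPRO at -1.06. Metallothioneins had a median of -0.21, at percentile 0.22 of random lists, with MT1M at -0.91, and PPAR targets -0.10. Entacapone had FSCN1 at 1.55, SPARC at 1.22 and GNG11 at 1.19, an endothelial median of 0.93, and MT1M at -0.82, AKAP12 at -0.81 and LTB4R at -0.78. Its fatty acid synthesis median of 0.11 lay above all random lists. Camera calls did not hold for tolcapone (adjusted p = 0.982 with an estimated correlation) or entacapone (adjusted p = 0.757 to 0.763 with an estimated correlation). Limma gave 3 and 29 genes at an unadjusted p under 0.05 for tolcapone and 2 and 25 for entacapone, and 9 and 3 genes differed by at least 2-fold.

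Tolcapone minus entacapone, at different doses, was 0.89 for GSTA3 (95% interval -0.37 to 2.15), 0.86 for CCDC141 (0.18 to 1.54) and 0.85 for IL1F10 (both under 2-fold the higher fibroblast signal with entacapone, so their sizes and ranks depend on the value added before taking logs), with CNNM3 at -0.94 (-1.98 to 0.11), TUBG1 at -0.81 (-1.30 to -0.31) and PTPRO at -0.79 (-1.39 to -0.20). SPARC was 0.69 higher with tolcapone (0.15 to 1.23) and CYP3A4 0.27 (-1.37 to 1.91). Fatty acid synthesis was at -0.15, below all random lists, and camera called no list. Limma gave 0 and 29 genes at an unadjusted p under 0.05, and 0 differed by 2-fold.

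Across the 3 pairs, the drugs known for liver injury were compared with their analogs with the pair as a block. CYP3A4 was 0.48 higher (SE 0.09, limma adjusted p = 0.734, higher in 3 of 3 pairs), as were TUBA1A at 0.58 (1.34, 0.01 and 0.41 for nefazodone, ibufenac and tolcapone minus their analogs) and PDK4 at 0.37, and TUBG1 was lower in 3 of 3 at -0.54. MLKL at 0.69 (2.03, 0.49 and -0.44, the first 2 against signals near that of the fibroblasts) and SPARC at 0.59 (1.38, -0.31 and 0.69) were higher in 2 of 3. The 15 PXR and CAR targets had a median of 0.13 and 13 were positive (camera adjusted p = 0.000586), which did not hold (adjusted p = 0.961 with an estimated correlation). Limma called 0 genes, with 278 at an unadjusted p under 0.05, and 20 without tolcapone and entacapone.

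**Figure D3:**
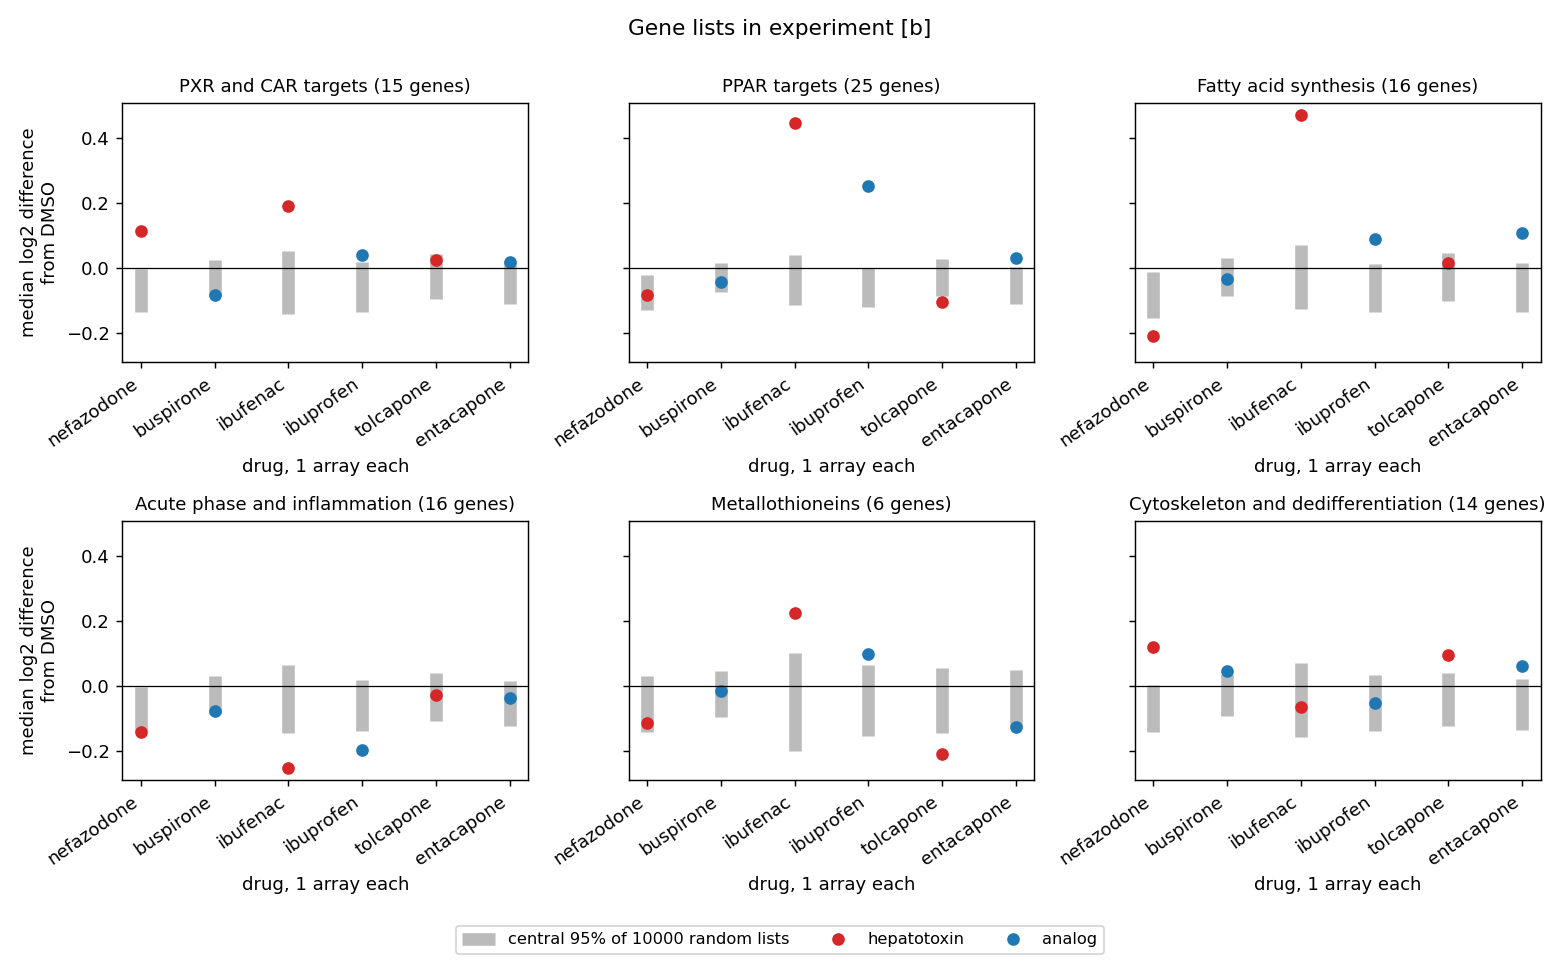
Median log2 difference from the DMSO array of experiment [b] for 6 gene lists and 6 drugs with 1 array each, with grey bars for the central 95% of 10000 random lists of like expression. PPAR targets lie at 0.45 with ibufenac and 0.25 with ibuprofen, and PXR and CAR targets at 0.11 with nefazodone and 0.19 with ibufenac.

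Some genes fixed for naming lay outside the tested set because their mean over all co-cultures lay under 1 log2 unit above the higher fibroblast array. For CYP1A1 that array, treated with troglitazone, read 323. CYP1A1 read 814 to 2350 in experiment [a] outside the low-signal arrays, 426 to 464 on those arrays and 209 to 268 in experiment [b]. These genes were fitted without the filters on fibroblast signal and on level, with the adjustment over all 19712 genes. Troglitazone minus DMSO was 0.35 for CYP1A1 (SE 0.12, limma adjusted p = 0.223), 0.51 for PLIN4 (SE 0.19), -0.73 for ANGPTL4 (SE 0.17), 0.33 for the stress factor DDIT3, -0.23 for HMOX1 and -0.61 for NQO1, and none passed.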

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

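The tests on CD163, on FSCN1, SPARC, GNG11 and TUBA1A and on troglitazone against time were chosen after the result was seen, as were all fits with a level for the low-signal arrays and, after the values of wider marker sets, the limit of 2-fold the fibroblast signal for markers; the tests of a single low or odd DMSO array were added after the other tests of their patterns had been seen.

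At 24 hours, 8 list medians and 18 of the genes chosen by the naming rule for this comparison had a difference between troglitazone and DMSO of the opposite sign to all 3 later pairs. Over all 5220 genes 1898 did so (36.4%). The difference between times was not tested for lists, and gene by gene limma called 0 genes, with 1184 at an unadjusted p under 0.05. The lists, at 24 hours, in the 2 pairs at 7 days and at 14 days, were bile acid genes (-0.108, then 0.36, 0.67 and 0.68), amino acid and urea metabolism (-0.118, then 0.28, 0.52 and 0.36), glucose metabolism (-0.044, then 0.06, 0.38 and 0.35), AHR targets (0.309, then -0.15, -0.10 and -0.36), p53 targets (0.16, then -0.58, -0.11 and -0.35), cell cycle (0.011, then -0.26, -0.15 and -0.26), 2 stellate cell genes (0.423, then -0.17, -0.08 and -0.79) and cholangiocyte markers (0.142, then -0.36, -0.24 and -1.71). Genes below 0 at 24 hours and above it later were CYP7A1 (-0.01, then 1.01, 1.19 and 3.21), BHMT (-0.011), CCND1 (-0.182), NDUFV1 (-0.101), OTC (-0.132), RDH16 (-0.088) and UQCRC2 (-0.066). Those above 0 at 24 hours and below it later were GDF15 (0.162, then -1.28, -0.85 and -1.11), CHORDC1 (0.322), CLDN4 (0.036), KRT19 (0.186), MCM4 (0.201), MIDN (0.013), MT1M (0.214), NFE2L2 (0.328), PLK2 (0.158), SLC7A5 (0.568) and TAGLN (0.195). In data outside the comparisons, the CYP1A1 probe set read 323 on the troglitazone-treated fibroblast array and 39.5 on the other fibroblast array, which most labels call untreated and whose title disagrees. These 2 arrays come from different experiments, hold mouse RNA on a human array, correlated at 0.752, and, among genes with a signal of at least 100 on the higher array, differed by at least 2-fold upward at 1019 and downward at 1026.

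With troglitazone CD163 was lower and CD14 higher than with DMSO. On the first arrays at 24 hours, 7 days and 14 days, CD163 read 147, 432 and 1560 with DMSO and 112, 101 and 205 with troglitazone. CD14 read 644, 298 and 155 with DMSO and 1090, 1260 and 711 with troglitazone. The CD163 difference thus came mostly from a rise with DMSO that was smaller with troglitazone. Fewer macrophages as the whole cause would lower their other markers by about as much, yet the 3 others with at least 2-fold the fibroblast signal, TYROBP at 0.47 (SE 0.20), C1QB at 0.54 (SE 0.28) and LYZ at 0.35 (SE 0.12), had a median of 0.47. The 6 further markers above the median level, such as VSIG4 and LAPTM5, lay near or under the fibroblast signal and decide nothing. Fibroblast RNA at the level of the pure fibroblast arrays cannot carry the CD163 signal, since the higher array had 12.4% of the lowest DMSO co-culture. Fibroblasts in co-culture were not measured apart, so a higher mouse signal there was not tested. A candidate explanation that stays open is a change of state of macrophages or of hepatocytes with the drug, which was not tested. A slower change with time under troglitazone, the hypothesis given below for all genes, also stays open and was not tested for these genes.

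With nefazodone, tolcapone and entacapone, FSCN1, SPARC, GNG11 and TUBA1A were higher than with DMSO, without passing limma's test. Mouse RNA at the level of the pure fibroblast arrays cannot carry these signals, as the higher fibroblast signal was at most 15.9% of the lowest of the 3 arrays. Neither fibroblast array received these drugs, so mouse RNA raised by them is not excluded. The shared DMSO array being low by itself is argued against by medians of 0.12 with buspirone, -0.01 with ibuprofen and -0.30 with ibufenac over the 4 endothelial markers with at least 2-fold the fibroblast signal. These markers had medians of 1.26 with nefazodone, 1.40 with tolcapone and 0.93 with entacapone, with CDH5 at 1.69, 1.81 and 1.35, FCN3 at 2.17, 2.36 and 1.86 and KDR at 0.83, 0.99 and 0.51 but EGFL7 at -0.17, 0.06 and -0.30, so more human endothelial cells on these 3 arrays may account for the genes. More human stellate cells or fibroblasts stay open, since 0 of their 11 markers had that signal, and whether the drugs or the plating of single cultures set the number of cells was not tested, with 1 array per drug.

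The troglitazone differences ran against the change with time. Between arrays that share no sample, Spearman's rho across genes of the 7-day repeat pair against DMSO at 14 days minus 24 hours was -0.74, and -0.73 after quantile normalization, which argues against shared arrays and array scale. Of the other pairs without a shared array, the first 7-day pair against the same time difference gave -0.69 and the 14-day pair against DMSO at 7 days minus 24 hours -0.54, so an odd repeat DMSO array is not enough. The 24-hour pair against DMSO at 14 days minus 7 days gave 0.03, and the drugs of experiment [b] -0.16 to 0.16. Slower loss of the early profile with troglitazone is a hypothesis that may fit these values, found and tested on the same data, and genes are not independent.

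Other splits of the same arrays bear on the counts. For troglitazone minus DMSO, 4 of 35 splits called at least 4 genes and the highest other called 1394, so chance is not excluded, and that split set the first 24-hour and 7-day arrays against the 14-day and repeat arrays, a structure of the samples. With the level for the low-signal arrays, 3 of 35 splits called at least 308, the highest other 1200, so this count does not exclude chance. The split with 1200 exchanges only the 24-hour arrays and keeps the drugs apart in 3 of 4 pairs, and the other, with 891, keeps them apart at 14 days and in the first 7-day pair, so both carry the drug difference, a structure of the samples. For rosiglitazone minus DMSO and troglitazone minus rosiglitazone the real count was 0, so all 35 splits reach it, with 16 and 0 as the highest of the others. At 7 days 6 of 56 splits reached 92 in the planned fit, the highest with 3201 genes following the low-signal arrays, and chance is not excluded. With the level, 2 of 56 reached 2538, the other being the mirror of the real split within the block at 2538, but both repeat arrays are 7-day arrays, and the 10 distinct splits of the other arrays are too few for a share under 0.05. At 14 days the 10 splits are too few for a share under 0.05, with 591 and 3234 genes in the 2 fits against 0 as the highest other, and so are the 10 splits of hepatotoxins and analogs, of which all 10 reached the real count of 0 and the highest other had 4.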

How the results depend on the processing

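The fits with a level for the 3 low-signal arrays, and those leaving out these arrays or a whole duration, were added after seeing the data. With 1 array in most groups and signals that differed between sets of arrays, counts of calls moved with the processing. Directions were followed only for named genes and lists already called in the fit with a level for the low-signal arrays, and not with arrays left out. Of these values 2062 kept direction and side of the threshold, 153 kept direction and lost the threshold and 4 reversed. Few reversals were likely from that choice, so directions are not shown to be steadier than counts. Of the counts, 308 stayed within 1.5 times and 93 moved. Counts of 0 that stayed 0 are among the 308 and tell nothing of stability. The cause was not tested unless stated. Genes near the signal of the fibroblast arrays are limited by signal over background. The filter removed genes whose mean over all co-cultures lay near that signal. Tested genes can still read near or under it on single arrays, as HSP90B1 did in experiment [a].

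For troglitazone minus DMSO the planned count of 4 became 0 after quantile normalization, 0 without the fibroblast filter, which tests more genes, 2 with a pseudocount of 1, 2 with every probe set, 25 with only the 2 groups, 308 with a level for the low-signal arrays, 2 without these arrays, and 1 to 122 leaving out each array in turn. With that level, the count of 308 became 59 at 2-fold or more, 551 after quantile normalization, 21 without the fibroblast filter, 33 with a pseudocount of 1, 492 with every probe set, 490 with an intensity trend, 1883, 0 and 1 without the arrays at 24 hours, 7 days or 14 days, and 0 to 1907 leaving out each array. Rosiglitazone minus DMSO went from 0 to 2 with only the 2 groups, 1 without the low-signal arrays and 0 to 5 leaving out each array, and with the level to 1 with an intensity trend and 0 to 1 leaving out each array. Troglitazone minus rosiglitazone went from 0 to 2 with only the 2 groups and 0 to 2 leaving out each array, and with the level to 168 without the arrays at 24 hours and 0 to 680 leaving out each array. Elevated rosiglitazone minus DMSO and troglitazone minus elevated rosiglitazone ranged from 0 to 91 and 0 to 238 leaving out each array in the planned fit.

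The replicate numbers cover only 2 pairs of 7-day arrays and the labels do not say that they pair cultures, and both arrays with number 2 belong to the low-signal set, so the correlation of 0.829 over 2 numbers between deviations from the group means follows that set. With the replicate number as a block limma called 308 genes for troglitazone minus DMSO, 2538 at 7 days and 3234 at 14 days, the counts of the fit with a level for the low-signal arrays, and 4516 for elevated rosiglitazone minus DMSO and 4548 for troglitazone minus elevated rosiglitazone. The elevated array carries replicate 1 although its signal is that of the repeat arrays, so its counts under this block hold the offset between sets.

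The 7-day count of 92 became 1521 after quantile normalization, 13 without the fibroblast filter, 2538 with the level for the low-signal arrays, 2312 without these arrays and 2 to 236 leaving out each array. With the level it became 309 at 2-fold or more and 1105 to 3095. The 14-day count of 591 became 2314 after quantile normalization, 3234 with the level, 3128 without the low-signal arrays and 231 to 1015 leaving out each array. With the level it became 821 at 2-fold or more and 5028 without the fibroblast filter.

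In experiment [b], genes at least 2-fold apart between the 2 arrays, without a test, numbered 5 for nefazodone, 1 for buspirone, 13 for ibufenac, 2 for ibuprofen, 9 for tolcapone, 3 for entacapone and 6 for nefazodone minus buspirone, against 0 calls. The hepatotoxins minus analogs had 4 calls with a pseudocount of 64, 10 with an intensity trend and 0 to 20 leaving out each pair. The medians that reversed were cytoskeleton genes in nefazodone minus buspirone (0.0249 after quantile normalization), oxidative phosphorylation at 7 days (-0.0285 after quantile normalization) and at 14 days (0.00603 with a pseudocount of 64) and cell cycle at 7 days (0.055 with a pseudocount of 64).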

Other observations

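The tests of genes that moved with time against the thiazolidinediones were chosen after the data were seen. Genes at least 2-fold higher in the DMSO culture at 14 days than in that at 24 hours numbered 991, and 879 of them (88.7%) were lower with troglitazone in the 7-day repeat pair, while of 393 genes at least 2-fold lower 386 (98.2%) were higher. Over all genes 51.6% were lower. Examples are KRT19, whose signal was 18, 85.1 and 1800 with DMSO at 24 hours, 7 days and 14 days and 22.7, 33.1 and 372 with troglitazone, and THRSP, at 9650, 1130 and 49.2 with DMSO and 12000, 9400 and 4090 with troglitazone. With rosiglitazone at 0.373 µg/mL, KRT19 read 18.6, 71.5 and 1170 and THRSP 8820, 2100 and 629. Elevated rosiglitazone on its single array read 17.4 for KRT19 against 71 on the repeat DMSO array, and its differences from that array had a Spearman's rho of -0.69 across genes with DMSO at 14 days minus 24 hours. This difference and that of the troglitazone repeat pair subtract the same DMSO array, and no pair free of it was measured with elevated rosiglitazone.

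Most genes of this paragraph were chosen after their values at 14 days were seen. The cytokine GDF15 and the transcription factor ATF3 had log2 changes of 4.005 and 2.86 and the hormone FGF21 2.23, while the list of 24 genes of the unfolded protein and integrated stress response had a median of 0.27, close to that of all genes, and of the 16 interferon genes 5 rose and 4 fell (median -0.05), with IFIT1, IFIT3, IFI44 and IFIH1 at -2.01, -1.23, -1.21 and -0.65 and IRF7, RIGI, GBP1, IFI27 and ISG15 at 1.36, 1.20, 0.85, 0.73 and 0.63. Lipid droplet gene CIDEC rose by 3.47 and the pantetheinase VNN1 by 2.55, while the glycolytic enzyme PKLR fell by 1.93 and the gluconeogenic enzyme G6PC1 by 1.47. All single genes here are from the fit with a level for the low-signal arrays and passed its test, and the median of all genes, 0.29, is not subtracted. These changes average the treatments, and for FGF21 the courses differed, from 10.2 to 51.8 with DMSO and from 22.3 to 364 with troglitazone. With DMSO at 24 hours FGF21 and CIDEC read 10.2 and 75.3, under 2-fold the higher fibroblast signals of 6.97 and 51.3. The sizes of their changes thus depend on the value added before taking logs.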
